A study of Ictidomys tridecemlineatus with 95 samples.

How the data were processed

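RNA editing from adenosine to inosine is a base change in RNA that reading by sequencing shows as an A-to-G mismatch. It was measured in the brain of the 13-lined ground squirrel, a mammal that hibernates, by RNA sequencing of forebrain, hypothalamus and medulla. The series holds 95 samples. The 90 brain libraries form 18 groups of 5, from 3 regions and 6 stages of the hibernation year, and come from 33 animals, of which 26 gave all 3 regions. The 3 neonate libraries and the 2 testes libraries are not analysed here. The labels give the stages as abbreviations, read here from knowledge of the study as summer active (SA), spring dark (SpD), interbout aroused (IBA), entering torpor (Ent), late torpor (LT) and arousing from torpor (Ar). Body temperature at sampling, per the labels, was 37.0 °C in SA and SpD, 30.6 to 37.4 °C in IBA, 23.0 to 27.0 °C in Ent, 5.5 to 6.6 °C in LT and 7.0 to 12.8 °C in Ar. Body temperature and time in torpor move together in this design.

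Libraries were made from polyadenylated RNA with a strand-specific Illumina TruSeq kit, per the labels' protocols, which refer to an earlier paper for housing and RNA extraction. The submitters' processing notes name bcl2fastq, cutadapt, STAR, Picard, GATK, StringTie and HISAT2, with no versions or roles. The genome build is not given in the sources used here, and positions are given on the contigs named in the deposited files. The deposited readme says that the transcriptome was built with StringTie and merged with TACO, that one set of sites was identified with a GATK approach and another with a hyper-editing approach (a search for reads with many A-to-G mismatches), and that predicted effects come from snpEff. The authors deposited counts of A (unedited) and G (edited) reads per site and library: 179295 GATK sites and 48863 hyperedited sites, 16975 of which are also in the GATK table. The deposited proportions are a fraction, G over the sum of G and A, and were used to check the counts. The deposited table of the authors' own tests gives a log2 fold change of the edited allele against LT for each stage, with a p-value and FDR from an edgeR likelihood ratio test, per the file headers. The deposited list of 85737 hyperedited sites gives counts of supporting reads, of a median of 2 reads per site. Site positions are 1-based; in that list 48863 sites match the count table once 1 is added to the start. The files used here list A-to-G sites alone, so the level of other mismatches is not used as a background. No genome was used, so the sequence around sites is not given.

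Reads at GATK sites summed to between 1089795 and 2532638 per library, with a median of 1639043; at hyperedited sites they summed to between 166505 and 457554. The editing level of a site in a library is the percentage of G reads. At the depth minimum of 10 reads a single library's level moves in steps of 10 points, so single libraries are imprecise and the tests use the read counts. Reads carry no molecular identifiers, so copies made in amplification count as separate reads. The p-values that rest on counts allow for such copies only as far as they add to the spread between libraries.

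Sites were tested within a region if at least 3 libraries of every stage had 10 or more reads (5 or more for hyperedited sites) and the level pooled over libraries lay between 1.0 and 99.0%. Each site was fitted with a quasi-binomial logistic model with 6 stage levels. Stage effects were tested with a quasi-likelihood F test, with the dispersion moderated across sites as limma does and never under 1. The contrasts were LT against IBA, Ent against IBA, Ar against LT, IBA against SA, and all 6 stages together, each with Benjamini-Hochberg adjustment over the sites of the region and a threshold of 0.05. A model of region and stage tested at the 12004 GATK sites shared by the 3 regions whether the LT against IBA change differed between regions. It had no term for animal, although the same LT and IBA animals gave all 3 regions. The mean editing level of a library is the unweighted mean over sites with 10 or more reads in every library of the region and a pooled level of 1.0 to 99.0%. Stages were compared with exact two-sided permutation tests of 5 against 5 libraries, whose smallest p is 0.00794, adjusted over 12 tests. Regions were compared within animals with 100000 random sign flips, adjusted over 3 tests. A site was called genotype-like where any library of the region had a level of 90.0% or more, since an inherited A-to-G difference from the reference genome gives levels near 0, 50 or 100% in an animal.

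Sites inside an exon or intron of the deposited transcriptome were told apart from those outside it, and effects were taken from snpEff; both are given where they differ. Named sites were chosen by a rule fixed before the data were examined: for LT against IBA, called sites in a gene with a symbol and with all 5 LT libraries above or below all 5 IBA libraries, ranked by the difference of mean levels, the first 10 higher and 5 lower, 1 per gene; for the other contrasts the first 5 each way; for hyperedited sites the first 5 each way; the 15 called amino-acid-changing sites with the largest LT against IBA difference; and every tested amino-acid-changing site in known recoding targets. The same rule over sites that are not genotype-like was added after the data were seen. The 20 gene lists fixed beforehand were glutamate receptors, GABA and glycine receptors, known recoding targets, RNA editing machinery, potassium channels, calcium and sodium channels, synaptic vesicle release, synaptic adhesion, cold and heat stress, innate double-stranded RNA sensing, mitochondria and energy metabolism, the circadian clock, the cytoskeleton, and markers of neurons, astrocytes, oligodendrocytes, microglia, endothelium and pericytes, choroid plexus and ependyma, and blood. Each list was tested by its number of genes with a higher site against 10000 random gene sets matched on tested sites per gene.

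Alternatives were depth minimums of 5 and 20 reads (10 for hyperedited sites), no filter on the pooled level, no genotype-like sites, only the 2 stages compared, sequencing lane or sex as a term, the replicate number as a block, a minimum difference of 5 percentage points, edgeR's quasi-likelihood test on allele counts, limma on arcsine square root levels, means pooled over reads or replaced by medians, each replicate left out, and each stage left out of the region comparisons. Those added after the data were seen left out IBA animals under 35 °C, used the larger of a site's own and the moderated dispersion, or repeated the named-site rule as above.

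The test was run on simulated counts in which 200 sites were raised in LT alone, against all other stages. These sites were not genotype-like and had pooled levels of 5 to 50.0%. In the data Ar levels lay near those of LT, so recovery there may differ. In the simulated forebrain, with 19192 sites, it recovered 3.2% of sites changed by an odds ratio of 2, 34.3% at 4 and 50.0% at 8, with 1 of 18992 unchanged sites called. In the simulated hypothalamus, with 21951 sites, recovery was 0.0, 14.5 and 52.9%, with 0 of 21751 unchanged sites called. In the simulated medulla, with 16816 sites, it was 0.0, 24.6 and 51.5%, with 3 of 16616 called. The test of region by stage, on 12004 sites raised in hypothalamus LT alone where changed, recovered 0.0, 14.5 and 29.2%, with 5 of 11804 called. On the simulated forebrain edgeR recovered 0.0, 6.0 and 24.3%, and limma 3.2, 23.9 and 51.4%.

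No pair of libraries of a group was a copy of another: chi-square per site was 10.56 or more for every pair. At 2453 variable sites, all 166 comparisons between regions matched each library best with the library of the animal it is labelled with. Software was Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and limma 3.58.1.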

Results

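RNA editing was followed in the forebrain, hypothalamus and medulla of 13-lined ground squirrels sampled in 6 stages of the year, from summer activity through spring to the torpor cycle, with 5 animals per region and stage. In torpor these animals let body temperature fall close to that of their surroundings, and rewarm in short arousals between bouts. The series title names editing that is sensitive to temperature. Reads at GATK sites came to a median of 1660547.5 per forebrain library, 1819252.5 per hypothalamus library and 1556628.5 per medulla library. After the depth filter 19192 forebrain, 21951 hypothalamus and 16816 medulla sites were tested. Genotype-like sites made up 35.9, 33.9 and 37.0% of them, so mean levels are given with and without such sites.

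Mean editing levels were higher in the cold stages of all 3 regions. With genotype-like sites left out, the forebrain mean over 5873 sites was 12.81% ± 0.09 (SD, n = 5) in IBA and 15.87% ± 0.69 in LT. In the hypothalamus it was 12.01% ± 0.23 in IBA and 16.03% ± 0.48 in LT over 7452 sites, and in the medulla 12.19% ± 0.19 and 15.06% ± 0.58 over 4626 sites. These LT minus IBA differences of 3.07, 4.01 and 2.86 percentage points passed the exact permutation test (adjusted p = 0.0238 in each region), and every LT library lay above every IBA library. With all sites the differences were 1.94 points in forebrain, 2.39 in hypothalamus and 1.59 in medulla (adjusted p = 0.0238 in each by exact permutation). Within single sequencing lanes they ranged from 1.79 to 2.24, from 2.1 to 2.68 and from 1.12 to 1.98. Over sites with 20 or more reads in every library the forebrain and medulla differences were 1.41 and 1.35 and no longer passed (adjusted p = 0.0635 and 0.0714 by exact permutation).

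**Figure D1:**
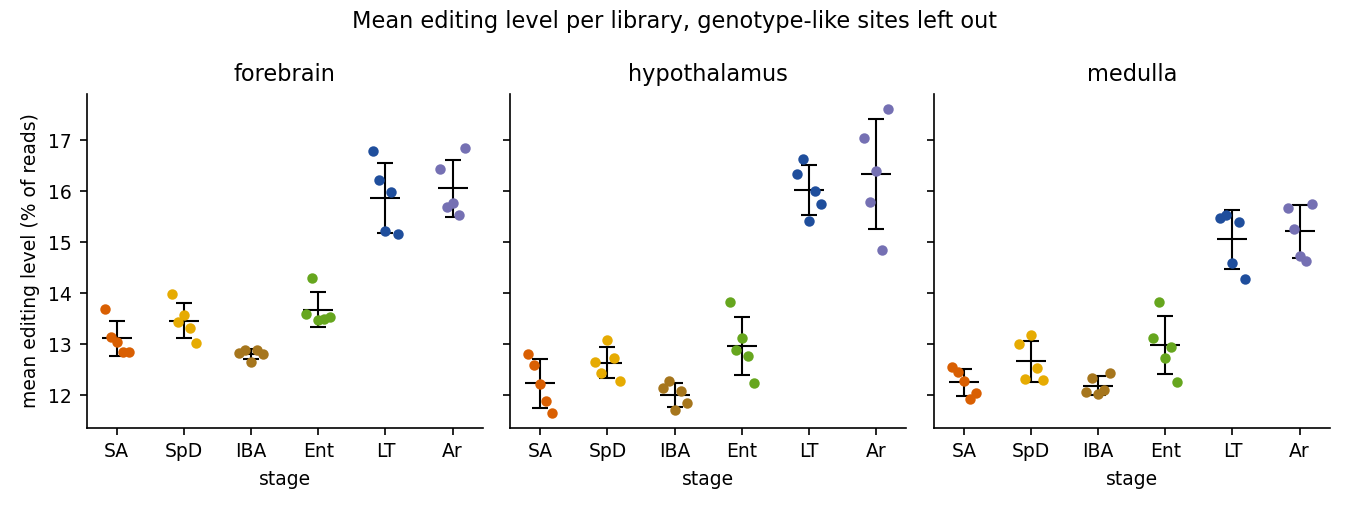
Mean editing level (percentage of reads, y axis) in each library by stage (x axis) for the 3 regions, genotype-like sites left out; points are libraries, bars the mean and SD of 5. The LT and Ar libraries lie above the IBA libraries in every region, with LT means of 15.87, 16.03 and 15.06% against IBA means of 12.81, 12.01 and 12.19%.

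The comparison of LT with IBA set the coldest stage against rewarmed animals of the same season. An intronic site in PKM, which encodes the glycolytic enzyme pyruvate kinase, rose from 13.1% ± 5.54 in IBA to 82.5% ± 7.36 in LT in the forebrain (n = 5 each, adjusted p = 3.88e-09). The same site (contig JH393281.1, position 31591638, minus strand) rose from 19.9% ± 10.8 to 79.9% ± 8.26 in the hypothalamus and from 14.5% ± 3.85 to 73.8% ± 8.59 in the medulla, at median depths of 52.0 and 65.0 reads. An intronic site in SPTBN4, a spectrin of axon initial segments and nodes of Ranvier (contig JH393471.1, position 2894863, plus strand), rose from 5.04% ± 5.03 to 63.2% ± 11.1 in forebrain, from 2.62% ± 4.01 to 57.6% ± 20.3 in hypothalamus and from 5.29% ± 5.13 to 64.5% ± 24.3 in medulla. In hypothalamus the ranking also held CEP170, a centrosomal protein (12.6% ± 9.94 to 92.8% ± 9.33), and GTF2H3, a subunit of the transcription factor TFIIH (15.0% ± 17.7 to 89.1% ± 7.19). It also held PXMP4, a peroxisomal membrane protein (9.16% ± 10.5 to 76.5% ± 13.5), and WDR26, part of a ubiquitin ligase complex (13.1% ± 11.2 to 80.3% ± 20.6). In medulla PXMP4 rose from 12.9% ± 21.7 to 82.8% ± 16.3, and the septin SEPT4 from 16.5% ± 7.51 to 78.0% ± 12.4. The endosomal chloride and proton exchanger CLCN3 rose from 12.1% ± 8.61 to 71% ± 11.3 and TXLNG, of the taxilin family, from 6.6% ± 4.45 to 56.7% ± 14.7. In forebrain RBM17, a splicing factor, rose from 11.6% ± 6.33 to 74.1% ± 13.6, PGAM2, a phosphoglycerate mutase, from 1.0% ± 2.24 to 60.6% ± 26.8, and CIPC, a repressor of the circadian CLOCK protein, from 24.8% ± 9.81 to 81.7% ± 19.0. All of these sites lie in introns by snpEff, though those in CEP170, PGAM2 and TXLNG fall inside assembled exons. Because a library reached 90% at them, the sites in CEP170, GTF2H3, PXMP4, WDR26, SEPT4, RBM17 and CIPC, and those in PKM and SPTBN4 in forebrain, count as genotype-like. The rule can also flag strongly edited sites. The PKM site counts as genotype-like in forebrain but not in medulla, although the same LT animals gave both regions.

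In total 511 forebrain sites passed, 484 of them higher in LT and 27 lower. The hypothalamus had 774, with 748 higher and 26 lower, and the medulla 192, with 180 higher and 12 lower. Higher sites lay in 170, 265 and 91 named genes. Their median level went from 5.76% to 33.33% in forebrain, from 4.71% to 35.18% in hypothalamus and from 4.79% to 37.48% in medulla. These sites were chosen on the same LT and IBA libraries, which widens the difference. With sequencing lane as a term the counts were 584, 798 and 203. The counts moved by more than 1.5 times with edgeR's test (96, 224 and 1), with limma in hypothalamus (1215) and medulla (327), and with only the LT and IBA libraries in the fit (132, 204 and 43). They also did with a depth minimum of 20 reads (245, 377 and 100) or of 5 reads in forebrain (861) and hypothalamus (1166), and without the IBA animals under 35 °C (203, 323 and 65). A single library also moved them: the forebrain count was 320 without IBA replicate 3, and the medulla count was 109 without LT replicate 2, 112 without LT replicate 1, 102 without IBA replicate 2, 127 without IBA replicate 3 and 111 without IBA replicate 5.

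Among the sites that were not genotype-like, chosen after the data were seen, the forebrain ranking added CAMK2A, a calcium-dependent kinase of synapses, which rose from 17.5% ± 11.2 in IBA to 70.0% ± 19.7 in LT. MICU1, a regulator of mitochondrial calcium uptake, rose from 22.6% ± 15.9 to 76.6% ± 14.3, and CLTA, a clathrin light chain, from 1.65% ± 2.28 to 53.8% ± 27.1. In RUSC2 the level rose from 23.9% ± 6.48 to 71.3% ± 8.73 and in CINP from 25.6% ± 19.6 to 72.5% ± 11.1. In the hypothalamus PSMD13, a proteasome subunit, rose from 15.3% ± 4.2 to 69.3% ± 6.5, MRPS10, of the mitochondrial ribosome, from 6.27% ± 7.22 to 60.9% ± 11.3, and RUFY2 from 10.9% ± 7.02 to 64.3% ± 3.54. GGT7 rose from 8.21% ± 6.85 to 62.3% ± 11.5 and ACIN1 from 9.22% ± 10.3 to 64.7% ± 14.9. PJA2, a ubiquitin ligase, rose from 15.2% ± 11.7 to 69.2% ± 9.54 there and, at another intronic position, from 18.8% ± 13.7 to 66.1% ± 19.1 in the medulla. In the medulla BMPR1A, a receptor for bone morphogenetic proteins, rose from 3.29% ± 3.26 to 52.3% ± 16.4 and MOB1A, of the Hippo pathway, from 3.26% ± 3.52 to 44.9% ± 9.74. These sites are intronic by snpEff except those in RUFY2, BMPR1A and MOB1A, which it places between genes and which fall inside assembled exons. Each level is over 5 libraries per stage.

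**Figure D2:**
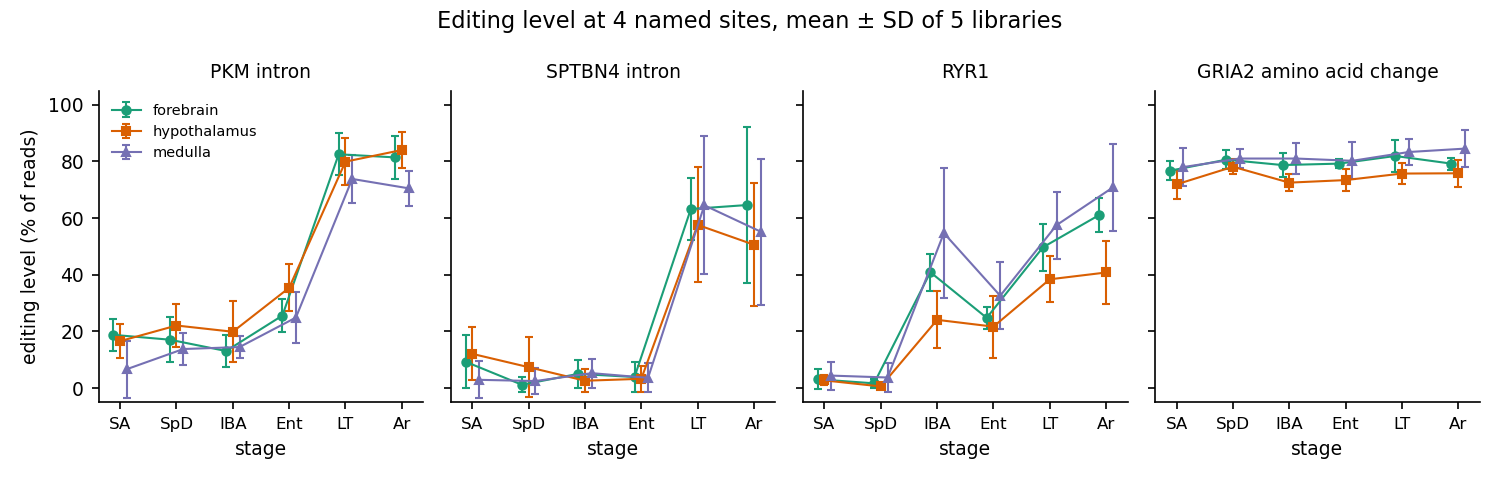
Editing level (percentage of reads, y axis) by stage (x axis) at the PKM and SPTBN4 intronic sites, the RYR1 site and the GRIA2 amino-acid-changing site; symbols are means and bars SDs of 5 libraries per region. PKM rises from 13.1% in IBA to 82.5% in LT in forebrain, RYR1 is at 3.13% in SA and 40.9% in IBA, and GRIA2 stays between 71.9 and 84.5% in all regions and the plotted stages.

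Some sites with the largest differences were genotype-like. A forebrain site in AZIN2, an antizyme inhibitor, was at 10.6% ± 23.8 in IBA and 92.6% ± 16.6 in LT, and also at 47.2% ± 36.0 in SA. RRAGD, a GTPase of the mTORC1 pathway, was at 28.9% ± 27.2 in IBA, 99.3% ± 1.6 in LT and 100% ± 0.0 in SA. ZBTB47 was at 16.6% ± 23.0 in IBA and 90.5% ± 21.2 in LT, the adenylate kinase AK4 at 10.9% ± 22.0 and 78.7% ± 19.9, and the potassium channel subunit KCNF1 at 42.8% ± 24.9 and 100% ± 0.0. The hypothalamus held such sites in PML, of nuclear bodies (2.0% ± 4.47 and 85.0% ± 25.3), in NKTR (9.11% ± 18.5 and 87.6% ± 25.1) and in the integrin ITGA6 (11.3% ± 21.8 and 83.0% ± 20.0). In the medulla NTRK2, the receptor of brain-derived neurotrophic factor, was at 41.7% ± 3.02 and 99.8% ± 0.34, and DZIP1L at 19.7% ± 19.6 and 84.3% ± 14.6. ATP9A, a phospholipid flippase, was at 0.123% ± 0.275 and 53.3% ± 3.18 there, at a synonymous site that is not genotype-like by the 90% rule. Of the lower sites, 77.8, 88.5 and 83.3% were genotype-like in forebrain, hypothalamus and medulla, against 13.2, 11.4 and 13.9% of higher sites. ADH7, an alcohol dehydrogenase, fell from 72.1% ± 25.2 to 0.0% ± 0.0 in forebrain, with Ar at 61.5% ± 23.2. SLC2A4RG fell from 71.4% ± 27.6 to 0.0% ± 0.0, GMEB2 from 68.9% ± 31.0 to 0.0% ± 0.0 and the kinase NEK9 from 92.4% ± 17.0 to 31.1% ± 28.6, while DNAJC5, a chaperone of synaptic vesicles, was at 54.1% ± 3.99 in IBA and 0.15% ± 0.335 in LT at a site not genotype-like by the rule. PSMA6, a proteasome subunit, fell from 100% ± 0.0 to 26.6% ± 16.9 in hypothalamus. Another NTRK2 site fell from 54.8% ± 1.62 to 0.127% ± 0.283 there.

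Sites in assembled introns were higher in LT more often than sites in assembled exons. With genotype-like sites left out, 9.22% of intronic and 2.53% of exonic sites were higher in LT in forebrain (Fisher's exact test, p = 2.28e-34). The shares were 9.33 and 3.58% in hypothalamus (p = 2.75e-30) and 4.46 and 0.95% in medulla (p = 7.61e-20, both by Fisher's exact test); sites are not independent of each other. Mean levels rose at both. At exonic sites the LT minus IBA difference was 2.73 points in forebrain, 3.56 in hypothalamus and 2.57 in medulla, and at intronic sites it was 7.76, 7.95 and 6.98 (exact permutation p = 0.00794 for each). The share of reads that fell on intronic sites was 5.82% ± 0.36 in LT and 6.19% ± 0.35 in IBA in forebrain, 6.75% ± 0.33 and 6.89% ± 0.32 in hypothalamus, and 5.79% ± 0.51 and 6.1% ± 0.45 in medulla (exact permutation p = 0.143, 0.46 and 0.341).

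**Figure D3:**
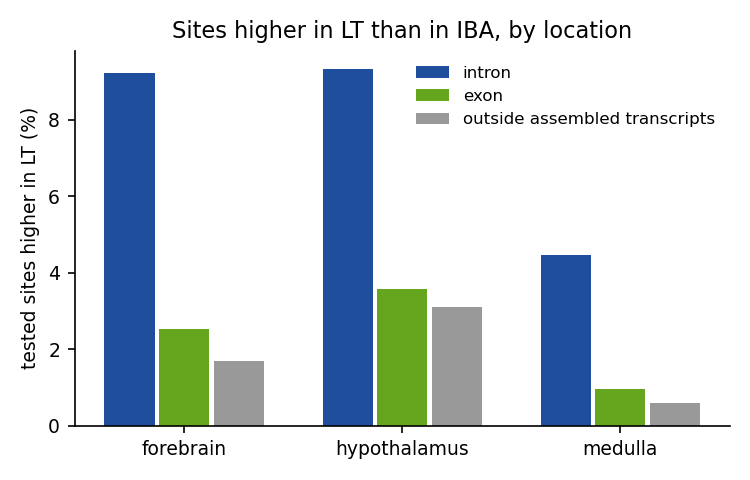
Percentage of tested sites that were higher in LT than in IBA (y axis) by region (x axis) and by location in the assembled transcriptome, genotype-like sites left out; each bar is a share of sites. Intronic bars reach 9.22, 9.33 and 4.46% against 2.53, 3.58 and 0.95% for exons.

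Sites that change an amino acid, synonymous sites and 3 prime UTR sites were each higher in LT less often than intronic ones. Of the amino-acid-changing sites that were not genotype-like, 0 of 344 in forebrain, 4 of 404 in hypothalamus and 2 of 358 in medulla were higher in LT, or 0.0, 0.99 and 0.56%, against 7.18, 8.05 and 3.25% of sites intronic by snpEff (Fisher's exact test, p = 6.56e-11, 9.48e-10 and 0.0023). The shares were 0.23, 0.58 and 0.23% of synonymous sites (Fisher's exact test, p = 4.97e-12, 4.44e-14 and 3.67e-05) and 1.14, 0.74 and 0.0% of 3 prime UTR sites (p = 6.04e-07, 1.11e-10 and 4.51e-05). Amino-acid-changing sites were not tested against these. In forebrain 344 of 828 amino-acid-changing, 432 of 1459 synonymous and 352 of 719 sites in 3 prime UTRs were not genotype-like. For introns by snpEff it was 3162 of 4149. The rule can miss inherited differences carried in a single copy, so the remaining classes may hold unequal shares of edited sites. Whether this accounts for the shares above was not tested. The same limit holds for assembled exons against introns. EIF3A, a subunit of a translation initiation factor (contig JH393296.1, position 8517456, minus strand), rose from 3.23% ± 2.37 to 14.2% ± 4.39 in hypothalamus and from 1.87% ± 0.838 to 8.22% ± 1.71 in medulla. It was at 3.91% ± 2.63 and 9.44% ± 5.3 in forebrain (adjusted p = 0.181). FLNB, an actin-binding filamin, rose from 18.6% ± 3.11 to 45.7% ± 14.0 in hypothalamus at position 8399514 of contig JH393283.1, but was at 39.7% ± 10.3 and 53.3% ± 5.42 in medulla (adjusted p = 0.237). The related FLNA, at a genotype-like site, rose from 77.9% ± 13.8 to 100% ± 0.0 in forebrain and from 51.2% ± 28.8 to 92.4% ± 9.61 in hypothalamus. GSK3B, a kinase of Wnt and insulin signalling, rose from 14.1% ± 3.08 to 30.2% ± 5.22 in medulla, and the adhesion protein AMIGO2 from 2.84% ± 2.8 to 14.5% ± 8.62 in hypothalamus. NEIL1, a DNA repair glycosylase, changed across the 6 stages in hypothalamus, with 25.0% ± 10.3 in IBA and 51.7% ± 20.5 in LT (adjusted p = 0.00439 across stages, 0.0757 for LT against IBA). ZC3H18, NFATC2IP and the GABA receptor subunit GABRA4 also changed across stages in hypothalamus without passing for LT against IBA, at 4.44% ± 3.06 and 13.3% ± 5.31, 4.63% ± 2.24 and 10.7% ± 2.0, and 3.4% ± 5.01 and 9.0% ± 12.4. So did a pair of SYTL5 sites at positions 4985216 and 4985217 (adjusted p = 0.0104 and 0.0198 across stages), at 15.8% ± 13.3 in IBA and 26.7% ± 4.19 in LT and at 6.47% ± 8.06 and 15.8% ± 8.98, and both were at 0.0% ± 0.0 in SA. AZIN2, ADH7, TMEM108 and NIPA1, also among the 15 ranked, were genotype-like.

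Most of the well-known recoding sites that were tested did not pass. The site in GRIA2, a subunit of AMPA glutamate receptors (contig JH393386.1, position 3933856), was at 78.7% ± 4.15 in IBA and 81.9% ± 5.78 in LT in forebrain, 72.5% ± 3.11 and 75.7% ± 3.66 in hypothalamus, and 81.0% ± 5.4 and 83.3% ± 4.66 in medulla (adjusted p = 0.589, 0.581 and 0.821). In HTR2C, the serotonin 2C receptor, the 4 tested sites were between 37.4 and 88.4% in the stage means of the 3 regions, and none passed. CYFIP2, of the WAVE actin regulatory complex, was at 71.2% ± 1.76 and 76.3% ± 5.7 in forebrain, CADPS, of dense-core vesicle release, at 34.5% ± 5.46 and 38.1% ± 3.17 in hypothalamus, and the splicing regulator NOVA1 at 68.6% ± 4.8 and 69.3% ± 3.5 in medulla. TMEM63B was at 49.7% ± 4.08 and 46.6% ± 8.33 in forebrain, and the kainate receptor subunit GRIK1 at 61.6% ± 6.71 and 61.4% ± 6.01 in hypothalamus. GRIK2 was at 68.3% ± 9.51 and 81.7% ± 1.96 there, IGFBP7 at 80.9% ± 5.61 and 78.6% ± 9.57 there, and the calcium channel CACNA1D at 24.8% ± 5.59 and 28.8% ± 7.06 in forebrain. None of these passed for LT against IBA, nor did the tested sites in TRO, BEST1, COPA and SPEG. Not passing does not show that these levels stayed the same. For changes by an odds ratio of 2, simulated recovery was 3.2% in forebrain and 0.0% in hypothalamus and medulla. Many of the sites above had higher levels than the simulated sites, so their recovery may differ. Recoding sites with pooled levels above the filter's upper limit were not tested, so almost complete editing is not covered here.

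The gene lists were described by the number of their sites that were higher in LT. Among known recoding targets 10 of 99 hypothalamus sites were higher, in 6 genes against 1.78 in matched random sets (permutation test over gene sets, p = 0.0042, adjusted p = 0.0798). Adjusted over the list alone, 15 were higher and 1 lower. Among them, outside the recoding positions, a GRIA2 site, intronic by snpEff, rose from 22.4% ± 10.9 to 53.5% ± 5.58. An intronic site in ADARB1, which encodes the editing enzyme ADAR2, rose from 26.5% ± 6.41 to 50.2% ± 6.71, and a genotype-like intronic GRIK2 site from 65.7% ± 12.3 to 89.9% ± 1.68. In forebrain 4 of 93 such sites rose, with 11 higher and 2 lower adjusted over the list alone, among them a synonymous site in the antizyme inhibitor AZIN1 (4.35% ± 2.38 to 11.7% ± 3.31), and in medulla 1 of 71, with 2 adjusted over the list alone. Glutamate receptors had 3 sites higher and 1 lower of 120 in forebrain, 6 higher of 101 in hypothalamus and 0 of 56 in medulla, and 7, 6 and 0 higher when adjusted over the list alone, with 2, 0 and 0 lower. GRIN1, an NMDA receptor subunit, rose from 10.9% ± 9.49 to 36.8% ± 7.39 in forebrain, at a site that overlaps TUBB4B. RNA editing machinery had 0 of 31, 2 of 37 and 0 of 26 sites higher in forebrain, hypothalamus and medulla, and 0, 3 and 0 adjusted over the list alone.

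Synaptic vesicle release had 3 of 44 sites higher in forebrain, 3 of 39 in hypothalamus and 0 of 34 in medulla, and 4, 7 and 1 adjusted over the list alone. BSN, a scaffold of the presynaptic active zone, rose from 5.11% ± 1.47 to 13.2% ± 3.35 in forebrain and from 4.37% ± 3.91 to 33.7% ± 10.8 in hypothalamus, and SNAP25, a SNARE protein, from 0.69% ± 1.54 to 15.4% ± 12.0 in hypothalamus. Mitochondria and energy metabolism had 8 of 34, 6 of 40 and 5 of 39 sites higher in the 3 regions, and 14, 11 and 12 adjusted over the list alone. The 8 forebrain and 5 medulla sites and 5 of the hypothalamus sites lay in ATP5B, a subunit of ATP synthase, where the leading intronic site rose from 1.08% ± 1.57 to 26.3% ± 16.4 in forebrain. SDHB, of succinate dehydrogenase, rose from 1.46% ± 3.27 to 18.3% ± 8.9 in hypothalamus. Innate sensing of double-stranded RNA had 3 of 40, 3 of 63 and 1 of 33 sites higher, and 7, 11 and 7 higher and 2 lower in each region when adjusted over the list alone. There MAVS, the adaptor of RIG-I-like receptors, rose from 5.49% ± 7.8 to 36.5% ± 11.5 in medulla, and EIF2AK2, the RNA-dependent kinase PKR, from 1.48% ± 3.31 to 32.9% ± 16.8 in hypothalamus. The cytoskeleton list had 3 of 58, 6 of 56 and 2 of 47 sites higher, in SPTBN4, FLNA and FLNB, and 3, 7 and 2 adjusted over the list alone. Calcium and sodium channels had 0 of 32, 1 of 41 and 1 of 25 (CACNA1B in hypothalamus and TRPM3 in medulla), and 0, 2 and 1 adjusted over the list alone. Synaptic adhesion had 0 of 44, 2 of 51 (NRXN2 and NLGN2) and 0 of 30, with the same counts adjusted over the list alone. Cold and heat stress had 0 of 29, 1 of 31 (DNAJB1) and 0 of 25, and 0, 2 and 1 adjusted over the list alone. Neuron markers had 2 of 30, 2 of 20 and 0 of 16, all in SNAP25, and 3, 5 and 1 adjusted over the list alone.

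Between LT and IBA no site passed in the genes listed for GABA and glycine receptors, potassium channels or the circadian clock, in any region. The same held for the listed markers of astrocytes, oligodendrocytes, microglia, endothelium and pericytes, and choroid plexus and ependyma. KCNF1 and CIPC, whose forebrain sites passed, are not among the listed genes. Adjusted over the list alone, 0 passed in all of these lists but the astrocyte markers. Those had 3 sites higher and 3 lower in forebrain, 2 and 3 in hypothalamus and 4 and 3 in medulla. Blood markers had 0 tested sites. No list passed over the lists of a region, with known recoding targets in hypothalamus the closest. Read shares at marker sites, a rough view of cell makeup, did not pass between LT and IBA for any cell type (lowest adjusted p = 0.125 by exact permutation). A single marker test could not pass: even the smallest possible p, 0.00794 by exact permutation, had an adjusted p of 0.125. These tests therefore cannot show that cell makeup stayed the same. Oligodendrocyte marker sites took 21.5 ± 7.95 reads per 10000 in LT and 14.5 ± 1.13 in IBA in forebrain (exact permutation p = 0.0238). Microglia markers took 0.778 ± 0.0722 and 0.589 ± 0.0901 in forebrain (exact permutation p = 0.0238) and 0.803 ± 0.147 and 0.47 ± 0.153 in hypothalamus (exact permutation p = 0.0159). These values rest on 1 site in 1 gene in each region. In medulla the 2 microglia sites took 1.51 ± 0.296 in LT and 1.51 ± 0.18 in IBA. Endothelial and pericyte markers took 3.89 ± 0.47 and 3.05 ± 0.205 in hypothalamus (exact permutation p = 0.00794, the smallest possible). Each of the marker tests whose p is given here had an adjusted p of 0.125.

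On entry to torpor mean levels were higher than in IBA, while few single sites passed. With genotype-like sites left out, Ent exceeded IBA by 0.87 points in forebrain (13.68% against 12.81%), 0.96 in hypothalamus (12.97% against 12.01%) and 0.79 in medulla (12.98% against 12.19%; exact permutation, adjusted p = 0.0238, 0.0381 and 0.0476). With all sites the forebrain difference of 0.77 points passed (adjusted p = 0.0238), while those of 0.59 in hypothalamus and 0.52 in medulla did not (adjusted p = 0.0571 and 0.163, exact permutation). Within lanes the all-site values ranged from 0.5 to 1.09, 0.09 to 0.92 and -0.25 to 1.03. Warm SpD animals also lay above IBA, at 13.47, 12.64 and 12.67% with genotype-like sites left out, close to Ent. Ent was not tested against SpD, so how much of its excess over IBA belongs to torpor entry cannot be told. The PKM site was at 25.6% ± 5.72 in Ent in forebrain and the SPTBN4 site at 3.93% ± 5.42, against LT levels of 82.5% and 63.2%. By site, 0 forebrain, 2 hypothalamus and 0 medulla sites passed with the quasi-binomial test, while 1969, 1875 and 1346 had an unadjusted p under 0.05. By edgeR no site passed and by limma 28 (15 higher and 13 lower in Ent), 0 and 4 (2 and 2) did. The 2 hypothalamus sites are named after their values were seen. The first was an intronic site in the gene ENSSTOG00000010508 (contig JH393297.1, position 16140344), which rose from 0.878% ± 0.973 in IBA to 10.7% ± 3.1 in Ent (adjusted p = 0.0222). The other was a genotype-like site in an assembled exon between genes (contig JH393414.1, position 4612004), which rose from 89.3% ± 2.47 to 96.3% ± 1.1 (adjusted p = 0.0463). With lane as a term 17 (13 higher and 4 lower), 3 (2 and 1) and 0 sites passed. Without Ent replicate 4 or 5 the all-site difference in hypothalamus was 0.67 or 0.66 points and passed (adjusted p = 0.0382, exact permutation). The hypothalamus count fell to 0 or 1 without any 1 library of either stage, and the medulla count was 3 without IBA replicate 4 and 2 without IBA replicate 5, all lower in Ent, and 1 without Ent replicate 5, which was higher.

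Arousing animals were still cold, and their levels lay near those of LT. Without genotype-like sites Ar was at 16.06% in forebrain, 16.34% in hypothalamus and 15.21% in medulla, above LT by 0.18, 0.32 and 0.16 points (exact permutation, adjusted p = 0.698 in each). Within lanes these values ranged from -0.35 to 0.62, -0.07 to 0.51 and -0.28 to 0.44, so the sign turned in every region. With all sites the differences were 0.33, 0.38 and 0.28 points (adjusted p = 0.371, 0.286 and 0.407), and within lanes 0.15 to 0.46, 0.25 to 0.37 and 0.21 to 0.26. Without Ar replicate 1 the all-site differences were 0.15, 0.23 and 0.08 points. PKM was at 81.4% ± 7.48, 84.0% ± 6.48 and 70.5% ± 6.19 in Ar in forebrain, hypothalamus and medulla, and SPTBN4 at 64.6% ± 27.4, 50.6% ± 21.7 and 55.2% ± 25.7. No site passed between Ar and LT by the quasi-binomial test or by edgeR, with 1187, 1176 and 978 at an unadjusted p under 0.05, and limma called 5, 2 and 5.

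**Figure D4:**
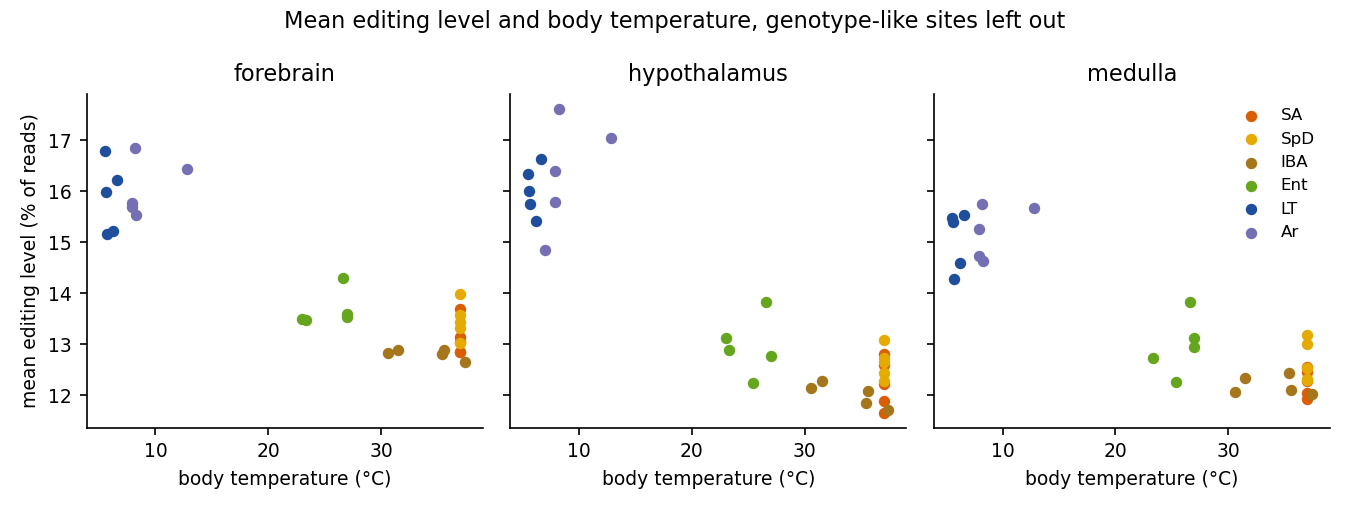
Mean editing level of each library (percentage of reads, y axis) against the animal's body temperature at sampling (°C, x axis), genotype-like sites left out; points are libraries, coloured by stage. LT libraries, at 5.5 to 6.6 °C, and Ar libraries, at 7.0 to 12.8 °C, lie within each region above the libraries of the other stages, all of which were sampled at 23.0 °C or more.

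IBA and SA animals are both warm, but differ in season and in recent torpor. The difference of mean level between them did not pass: IBA minus SA was -0.45 points in forebrain, -0.22 in hypothalamus and -0.16 in medulla with all sites (exact permutation, adjusted p = 0.159, 0.214 and 0.492), and -0.99 to -0.12, -0.31 to -0.07 and -0.42 to 0.23 within lanes. A few sites differed. An exonic site in RYR1, the ryanodine receptor calcium channel (contig JH393611.1, position 1270243, plus strand, intronic by snpEff), rose from 3.13% ± 3.46 in SA to 40.9% ± 6.53 in IBA in forebrain (adjusted p = 1.04e-06), from 2.74% ± 1.8 to 24.1% ± 10.0 in hypothalamus and from 4.43% ± 4.94 to 54.7% ± 23.0 in medulla, where it is genotype-like. CPLX2, a complexin of synaptic vesicle fusion, rose in forebrain from 0.11% ± 0.0792 to 8.53% ± 1.32 at a median depth of 1105.5 reads. ADAM22, a synaptic receptor for LGI1, rose from 2.08% ± 1.75 to 17.7% ± 2.83, CFAP36 from 4.75% ± 1.5 to 17.1% ± 5.59, and an amino-acid-changing site in PLEKHM2, a lysosome adaptor of kinesin-1, from 0.0922% ± 0.206 to 8.9% ± 3.69. An amino-acid-changing site in SYTL5, a RAB27 effector, rose from 4.06% ± 3.07 to 32.5% ± 12.2 in hypothalamus and from 3.82% ± 3.82 to 35.8% ± 7.89 in medulla. ADCYAP1, which encodes the neuropeptide PACAP, rose from 12.2% ± 3.14 to 34.3% ± 6.34 in hypothalamus and from 9.37% ± 3.05 to 31.2% ± 4.78 in medulla. HCFC2 (5.09% ± 5.39 to 55.9% ± 18.3) and SBF2 (7.56% ± 2.83 to 35.8% ± 6.68) rose in hypothalamus, and MCF2L2 (1.6% ± 2.28 to 21.9% ± 5.69) and the proline transporter SLC6A20 (18.8% ± 5.15 to 36.0% ± 4.04) in medulla. These sites fall inside assembled exons; snpEff places those in ADAM22, CFAP36, CPLX2, ADCYAP1 and SLC6A20 between genes. The genotype-like NTRK2 site fell from 100% ± 0.103 to 46.8% ± 6.34 in forebrain.

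In total 24 forebrain sites passed between IBA and SA (20 higher and 4 lower in IBA), 23 hypothalamus sites (all higher) and 13 medulla sites (all higher). The forebrain count moved by more than 1.5 times with lane as a term (39), edgeR (14) and limma (42) and without the IBA animals under 35 °C (11). It was 11 without SA replicate 3, SA replicate 4 or IBA replicate 3, 13 without SA replicate 5, 14 without SA replicate 2 and 15 without IBA replicate 5. The fit of only these 2 stages called 12 higher and 10 lower in forebrain, 24 and 7 in hypothalamus and 7 and 8 in medulla, so the excess of higher sites was kept in hypothalamus, smaller in forebrain and absent in medulla in that fit.

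Hyperedited sites, found from reads with many mismatches, gave the same direction. They were read in the same libraries, and 16975 of the 48863 are also GATK sites, so the 2 sets are not independent. In forebrain 416 of 7893 tested sites passed between LT and IBA (406 higher and 10 lower), in hypothalamus 620 of 9133 (606 and 14) and in medulla 156 of 6288 (154 and 2). The mean level rose by 3.91, 4.95 and 2.93 points (exact permutation, adjusted p = 0.019 in each). In forebrain FAM213A, a redox protein, rose from 0.0% ± 0.0 to 58.8% ± 33.6 and CLCN3 from 6.19% ± 8.52 to 69.4% ± 14.9. PJA2 rose from 8.54% ± 10.2 to 70.0% ± 15.4, TUBE1, a tubulin, from 9.98% ± 11.4 to 65.8% ± 15.1, and NRF1, a regulator of mitochondrial genes, from 16.2% ± 12.1 to 80.6% ± 25.8. In hypothalamus POLR2I, an RNA polymerase II subunit, rose from 11.2% ± 15.3 to 88.0% ± 11.1 and MFN1, of mitochondrial fusion, from 10.6% ± 16.1 to 87.4% ± 19.0. SPG7, a mitochondrial protease, rose from 10.8% ± 10.9 to 80.7% ± 11.1 and ABHD18 from 13.0% ± 12.9 to 81.3% ± 19.2. In medulla another POLR2I site rose from 13.9% ± 15.0 to 79.9% ± 23.1, IFT46, of cilia, from 17.9% ± 18.7 to 83.8% ± 17.7 and PCSK7, a proprotein convertase, from 9.47% ± 8.89 to 71.2% ± 32.5. NUP54, a nuclear pore protein, fell from 28.6% ± 10.2 to 3.39% ± 3.4 in forebrain. Depths were low here, with medians of 6.0 reads per library in FAM213A, 8.5 in CLCN3 and 7.0 in IFT46. By name these sites are genotype-like except those in FAM213A and NUP54. The counts moved by more than 1.5 times with edgeR (274, 365 and 57), a depth minimum of 10 reads (218, 331 and 102), the larger of own and moderated dispersion (150, 181 and 34) and without the IBA animals under 35 °C (222, 329 and 83), and with limma in medulla (87).

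Within animals the regions differed little in mean level. Forebrain exceeded hypothalamus by 0.15 points (33.63 and 33.48% at 9066 sites, higher in 19 of 27 animals; permutation test, adjusted p = 0.0122), a difference that turned over pooled reads (-0.14) and at 20 or more reads (-0.02) and did not pass without genotype-like sites (0.18, adjusted p = 0.0845) or without SA (0.1), SpD (0.11) or Ent (0.13). Forebrain exceeded medulla by 0.26 points in 25 of 29 animals (adjusted p = 3e-05; 0.02 points at 20 or more reads, adjusted p = 0.689, and 0.2 over pooled reads, adjusted p = 0.0512), and hypothalamus exceeded medulla by 0.18 points in 21 of 27 (adjusted p = 7.65e-04; 0.54 points over pooled reads, adjusted p = 3e-05, and 0.1 at 20 or more reads, adjusted p = 0.0102). The rise from IBA to LT was larger in hypothalamus than in medulla by 0.39 points at shared sites of the same animals (exact permutation p = 0.00794, adjusted p = 0.0238), while forebrain minus hypothalamus (-0.23) and forebrain minus medulla (0.17) did not pass (adjusted p = 0.167 and 0.206 by exact permutation). No hypothalamus library shared a lane number with a library of another region, so lane and region cannot be told apart for that region. Forebrain and medulla libraries shared lane numbers 1 and 3. A shared number does not show a shared sequencing run, so the same limit may hold for them. At the 12004 sites tested in all regions, no site passed the quasi-binomial test for a different LT against IBA change between regions, and 317 had an unadjusted p under 0.05. That model does not pair the regions by animal, unlike the comparison of mean rises. Other tools were not run on it. Of the higher sites, 228 were shared by forebrain and hypothalamus where 14.0 would be shared by independent lists, 78 by forebrain and medulla (2.93) and 97 by hypothalamus and medulla (4.49). In 66 sites, PKM and SPTBN4 among them, the rise was called in all 3 regions; the regions come from the same animals, so the lists are not independent.

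Across all 6 stages 994 forebrain, 1584 hypothalamus and 580 medulla sites passed. At sites higher in LT and not genotype-like, the median forebrain level was 5.17% in SA, 6.27% in SpD, 4.41% in IBA, 9.45% in Ent, 29.2% in LT and 30.96% in Ar. The choice of these sites lowers the IBA value and raises the LT value. The counts moved by more than 1.5 times with edgeR (433, 714 and 143), a depth minimum of 20 reads (507, 753 and 310) and, in forebrain and hypothalamus, 5 reads (1642 and 2507). In medulla the FLNB amino-acid-changing site at position 8399504 changed across stages, from 40.7% ± 8.35 in SA to 59.3% ± 5.93 in LT (adjusted p = 0.0209). The authors' deposited table lists 5113, 6516 and 2047 sites with an FDR under 0.05 of 86147, 94357 and 79543 tested. Of these, 1302, 1855 and 628 passed the depth filter used here. Among sites called here across the 6 stages, 798 of 994, 1267 of 1584 and 371 of 580 are on the authors' list. Of those called here between LT and IBA, 412 of 511, 633 of 774 and 137 of 192 are on it. All of the latter calls had the same direction of IBA against LT in the authors' deposited table. Both sets of tests rest on the same libraries, so overlap and shared direction are not independent support.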

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

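The test of read depth below was planned before its result was seen; the splits of the samples and the tests of genotype, unspliced reads, body temperature, less editing in the cold, lane and size of the rise were chosen after the results they bear on were seen.

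A single library stood apart from the other 4 in 1 of 18 groups of mean levels and in 33 of 206 groups of levels at named sites. Chance gives about 5% for independent values with a normal spread. Levels at many of these sites lie near 0, 50 or 100%, and the regions share animals. For the named sites 5% is therefore not the chance rate. In the mean levels the separate library was medulla Ar replicate 1, at 35.14% against 33.99 to 34.23% in the others. Many of the named sites are genotype-like. In forebrain AZIN2 was at 62.9% in 1 LT library (others 100%) and at 53.1% in 1 IBA library (others 0.0%), ZBTB47 at 52.5% and RRAGD at 96.4% in 1 LT library, and NEK9 at 62.1% and AK4 at 50.0% in 1 IBA library. In hypothalamus AZIN2 was at 35.6% in 1 LT and 31.2% in 1 IBA library, NKTR at 42.9 and 42.1%, PML at 41.7 and 10.0%, ZBTB47 at 47.7% in 1 LT library and ITGA6 at 50.0% in 1 IBA library. PXMP4 was at 50.0% in 1 medulla IBA library (others 0.0 to 14.3%).

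At sites near 0 or 100% the separated library lay close to the rest. These were PGAM2 (5.0% in forebrain IBA), DNAJC5 (0.7% in forebrain LT), PLEKHM2 (0.5% in forebrain SA), NTRK2 (99.8% in forebrain SA and 99.2% in medulla LT at position 406969, and 0.6% in hypothalamus LT at position 403819), ATP9A (0.6% in medulla IBA), ADH7 (0.7% in medulla LT at position 3486326) and GMEB2 (4.8% in medulla LT). GTF2H3 was at 10.0% (position 1183046) and WDR26 at 4.0% (position 1440048) in 1 hypothalamus IBA library, with the others at 0.0%. These GTF2H3 and WDR26 positions are other sites than those whose levels the report gives. Wider gaps were seen at sites in PKM (38.3% in 1 hypothalamus IBA library, others 9.5 to 17.6%), WDR26 (100% in hypothalamus LT at position 1440048, others 35.0 to 53.3%), RUFY2 (70.6% there, others 61.8 to 63.2%), SBF2 (12.5% in hypothalamus SA, others 5.8 to 7.4%), SEPT4 (73.1% in medulla LT at position 4605711, others 42.1 to 46.2%), SLC6A20 (43.1% in medulla IBA, others 32.7 to 35.0%) and the hyperedited SPG7 site (100% in hypothalamus LT, others 71.9 to 78.9%).

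Levels were higher in LT than in IBA in all 3 regions. Animal genotype is unlikely to be the whole cause, since without genotype-like sites the smallest difference over the regions was 2.86 points. The genotype-like rule can miss inherited differences carried in a single copy. Ar libraries, from other animals than LT, also exceeded IBA at these sites, by 3.25, 4.33 and 3.02 points in forebrain, hypothalamus and medulla. At sites in assembled exons the smallest difference was 2.57 points. Unspliced RNA covers exons as well, so this does not exclude a larger share of unspliced reads. The share of reads on intronic sites was not higher in LT. It was 5.82, 6.75 and 5.79% in forebrain, hypothalamus and medulla, against 6.19, 6.89 and 6.1% in IBA. Low body temperature may account for the pattern: Ar, still cold, reached at least 1.05 times the rise from IBA to LT, while SA and SpD, both warm, lay at 0.22 of it or less. Temperature and time spent in torpor cannot be told apart in these stages, so a slower loss of edited RNA, or another change of the torpid brain, stays open and was not tested.

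Fewer sites were lower in LT. Animal genotype may account for most of them: 82.9% of single-library levels at these 65 calls (42 distinct sites, some called in more than 1 region of the same animals) lay within 10 points of 0, 50 or 100%, and 54.1% of those near 50 or 100%, against 57.7 and 24.9% at higher sites. All 5 Ar libraries lay below all 5 IBA libraries at 16.9% of the calls (11 of 65; 9 of the 42 distinct sites), against 0.27, 0.21 and 0.19% of all tested sites, but the sites were chosen on the same IBA libraries, which raises the share. In stages outside that choice, the mean of SA and SpD minus Ar had a median of -0.1, 0.0 and -0.25 of IBA minus LT in forebrain, hypothalamus and medulla, against 0.88, 0.89 and 0.89 at higher sites. Less editing in the cold is therefore excluded as the cause of the whole set, but stays open for single sites.

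More sites passed in hypothalamus than in medulla, and the rise of mean level at shared sites was larger in hypothalamus by 0.39 points (exact permutation p = 0.00794, adjusted p = 0.0238; 0.71 points without genotype-like sites). Read depth is excluded as the cause only at the 13601 sites tested in both regions. With reads matched site by site there, the hypothalamus count (246 higher and 10 lower) was 2.72 times that of the medulla (89 and 5), and 2.26 times with all reads. Of the 748 higher hypothalamus sites, 407 are among these sites. Depth also sets which sites are tested, 21951 in hypothalamus and 16816 in medulla, and its effect through that filter was not tested. A larger rise in hypothalamus, the region difference of 0.39 points, may account for the count. Sequencing lane cannot be told apart from region, since 0 lane numbers were shared by hypothalamus and medulla libraries. No single site passed the region by stage test by the quasi-binomial model at 12004 sites, where 317 had an unadjusted p under 0.05. That model does not pair the regions by animal.

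Chance as the cause of the counts was tested with 100 splits of the samples for each, the real split included. Only 1 of the 100, the real split, gave as many sites for LT against IBA (511, 774 and 192 in forebrain, hypothalamus and medulla; highest of the other splits 8, 1 and 1), for the 6 stages (994, 1584 and 580; highest 5, 6 and 3), for IBA against SA (24, 23 and 13; highest 1, 1 and 2) and for hyperedited sites (416, 620 and 156; highest 72, 97 and 15). Chance is excluded for these counts. For Ent against IBA in hypothalamus (2; highest 1) it was also 1 of the 100, but by a margin of 1 site. That count was 0 with edgeR and limma and at most 1 without any 1 library, so chance is left open there. Where the count was 0, by the quasi-binomial test, 100 of 100 splits gave as many. These were Ent against IBA in forebrain and medulla (highest other split 3 and 1), Ar against LT in forebrain, hypothalamus and medulla (5, 1 and 2), and the region by stage test (2).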

How the results depend on the processing

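Leaving out IBA animals under 35 °C, the larger of own and moderated dispersion, and the named-site rule over sites that are not genotype-like were chosen after the data were seen; the other alternatives were fixed before the data were examined. Over the alternatives, 572 values for comparisons kept direction and side of the threshold, or stayed within 1.5 times for counts. Another 92 counts moved further, 6 values reversed, 5 came to pass and 8 no longer passed. For named sites together with counts by gene list, location and gene, 7920 values were kept and 0 reversed. Another 337 of those counts moved further, and of the named sites 22 came to pass and 675 no longer passed. Of sites called in 1 contrast, 84 did not pass with edgeR (47 did), 67 with only the 2 stages compared (48 did) and 56 without IBA animals under 35 °C (75 did). The latter 2 fits use fewer samples; for other changes the cause was not tested.

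For LT against IBA the counts in forebrain, hypothalamus and medulla were 245, 377 and 100 at a depth minimum of 20, 132, 204 and 43 with only the 2 stages, 203, 323 and 65 without IBA animals under 35 °C and 96, 224 and 1 with edgeR. They were 861 in forebrain and 1166 in hypothalamus at a depth minimum of 5, and 1215 in hypothalamus and 327 in medulla with limma. Over the 6 stages they were 507, 753 and 310 at depth 20 and 433, 714 and 143 with edgeR, and 1642 in forebrain and 2507 in hypothalamus at depth 5. Stricter depth minimums test fewer sites. Hyperedited counts were 218, 331 and 102 at a depth minimum of 10, 150, 181 and 34 with the larger dispersion, 222, 329 and 83 without IBA animals under 35 °C and 274, 365 and 57 with edgeR, and 87 in medulla with limma.

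For Ent against IBA forebrain had 8 sites at depth 20 (7 higher and 1 lower in Ent), 3 with only the 2 stages (1 and 2), 17 with lane as a term (13 and 4) and 28 with limma (15 and 13). The hypothalamus count of 2 was 1 at depth 5, with sex as a term, without genotype-like sites or with the larger dispersion, and 0 without IBA animals under 35 °C, with edgeR or with limma. With only the 2 stages it was 4, of which 3 were lower. Medulla had 1, lower, with only the 2 stages and 4 with limma (2 higher and 2 lower). For Ar against LT forebrain had 3 with only the 2 stages, 2 with lane as a term and 5 with limma, hypothalamus 2 with limma, and medulla 2 with only the 2 stages and 5 with limma. For IBA against SA forebrain had 39 with lane as a term, 11 without IBA animals under 35 °C, 14 with edgeR and 42 with limma, and in medulla only the 2 stages gave 15, of which 8 were lower.

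At a depth of 20 in every library the LT minus IBA mean was 1.41 points in forebrain (adjusted p = 0.0635) and 1.35 in medulla (0.0714). Ent minus IBA in hypothalamus came to pass with pooled reads (1.71) and without genotype-like sites (0.96, both 0.0381), and in medulla without genotype-like sites (0.79, 0.0476). Ar minus LT in hypothalamus was -0.16 with pooled reads (0.952). Forebrain minus hypothalamus was -0.14 with pooled reads (0.0512), -0.02 at depth 20 (0.689), 0.18 without genotype-like sites (0.0845), and 0.1, 0.11 and 0.13 without SA, SpD and Ent (0.0937, 0.0878 and 0.0545). Forebrain minus medulla was 0.2 with pooled reads (0.0512) and 0.02 at depth 20 (0.689).

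Leaving out 1 library gave 320 to 497 sites for LT against IBA in forebrain (320 without IBA replicate 3) and 102 to 161 in medulla (109 and 112 without LT replicates 2 and 1, and 102, 127 and 111 without IBA replicates 2, 3 and 5). IBA against SA in forebrain had 11 to 20 (11 without SA replicate 3 or 4 or IBA replicate 3, 13 and 14 without SA replicates 5 and 2, 15 without IBA replicate 5). Ent against IBA had 0 to 1 in hypothalamus, where the 1 site without IBA replicate 5 was lower, and 0 to 3 in medulla (3, all lower, without IBA replicate 4). The hypothalamus mean for Ent minus IBA was 0.52 to 0.67, and passed without Ent replicate 4 (0.67) or 5 (0.66). Other counts stayed within 1.5 times, and other differences of mean level kept their calls, when any 1 library was left out. The Ar minus LT mean was 0.15, 0.23 and 0.08 points in forebrain, hypothalamus and medulla without Ar replicate 1.

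Replicate numbers do not pair the samples: the correlation of same-numbered LT and IBA libraries was as low as -0.082, -0.092 and -0.084 and at most 0.122, 0.11 and 0.105 in forebrain, hypothalamus and medulla. With the replicate block the counts were 599, 802 and 233 for LT against IBA, 34, 11 and 7 for Ent against IBA (26 higher and 8 lower, 6 and 5, and 2 and 5), 2, 8 and 4 for Ar against LT, and 260 and 68 hyperedited sites in forebrain and medulla.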

Other observations

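The tests of clustering were planned before their results were seen; the tests of levels kept after torpor, of genotype and of a level linear in temperature (for Ent, then for SpD and Ar) were chosen after, as were the sites described next.

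The levels of some sites over the other stages follow; whether their courses differ was not tested. BSN, the presynaptic scaffold, had forebrain levels of 1.41% ± 0.429 in SA, 1.57% ± 1.3 in SpD, 5.11% ± 1.47 in IBA, 8.16% ± 1.6 in Ent, 13.2% ± 3.35 in LT and 16.5% ± 5.21 in Ar (SD, n = 5). In hypothalamus it was at 4.14% ± 2.5 in Ent and 30.4% ± 9.94 in Ar. NRXN2, a presynaptic adhesion protein, was at 0.0% ± 0.0 in IBA, 15.2% ± 14.2 in Ent, 33.2% ± 21.8 in LT and 40.5% ± 16.4 in Ar in hypothalamus. ACIN1 was at 64.7% ± 14.9 in LT and 30.9% ± 13.1 in Ar there, and a SEPT4 site in medulla (position 4605711) at 50.4% ± 12.7 and 76.4% ± 5.25; neither is among sites called between Ar and LT, where the quasi-binomial test and edgeR called 0, limma called 2 and 5, and 1176 and 978 sites had an unadjusted p under 0.05. In forebrain CIPC, a circadian repressor, was at 50.0% ± 11.8 in SpD and 46.5% ± 22.4 in Ent, between 24.8% ± 9.81 in IBA and 81.7% ± 19.0 in LT.

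Over all higher sites that were not genotype-like, median levels in hypothalamus were 5.11% in SA, 5.26% in SpD, 4.03% in IBA, 8.92% in Ent, 32.29% in LT and 30.77% in Ar, and in medulla 4.12, 5.51, 3.82, 10.34, 33.78 and 30.89%. The sites were chosen on the same LT and IBA libraries, which lowers the IBA values and raises those of LT. Hyperedited mean levels were 16.0% ± 0.49 in Ent and 19.34% ± 0.63 in Ar in forebrain, 15.44% ± 0.47 and 19.84% ± 0.92 in hypothalamus, and 14.08% ± 0.41 and 16.68% ± 0.42 in medulla.

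A hypothesis is that editing level follows body temperature in a straight line. Ent lay at 0.28, 0.24 and 0.28 of the rise from IBA to LT in forebrain, hypothalamus and medulla, against 0.31, 0.32 and 0.29 from the mean body temperatures of the stages, so the largest distance for Ent was 0.08. Ar lay at 1.06, 1.08 and 1.05 against 0.89, 0.9 and 0.89, or 0.52, 0.72 and 0.47 points above the line (standard errors 0.37, 0.52 and 0.33). SpD, at 37.0 °C, lay above IBA, at a mean of 34.1 °C, by 0.66, 0.63 and 0.48 points (exact permutation p = 0.00794, 0.0159 and 0.0476, not adjusted), where the line puts it below. All these values leave out genotype-like sites. With all sites SpD minus IBA was 0.2, 0.14 and 0.01 points, and at hyperedited sites 0.75, 0.48 and -0.2. A straight line is therefore neither supported nor excluded, and cannot be told apart from time in the torpor cycle.

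Another hypothesis is that sites higher in IBA than in SA hold levels from the preceding torpor, or from the season, in warm animals. Of these 56 calls over the regions (35 distinct sites), 1.8% are genotype-like. An inherited difference carried in a single copy can stay below the level that this rule requires. The rule therefore cannot exclude animal genotype for these calls. At 64.3% of the calls (36 of 56) all 5 Ent libraries also lay above all 5 SpD libraries, against 0.53, 0.5 and 0.47% of all tested sites in forebrain, hypothalamus and medulla. The same animals gave the regions, and of the 35 distinct sites this held for 15 in every region called and for 20 in any. RYR1 in forebrain was at 1.7% ± 1.67 in SpD, 40.9% ± 6.53 in IBA, 24.8% ± 3.95 in Ent, 49.7% ± 8.31 in LT and 61.1% ± 6.0 in Ar, and SYTL5 in hypothalamus was at 9.06% ± 8.3, 32.5% ± 12.2, 34.1% ± 6.38, 32.9% ± 12.9 and 35.0% ± 6.9. Levels kept after torpor may account for this; season may as well, since SA and SpD animals differ from the others in both.

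Higher sites lay close together. Of those not genotype-like, 49.5% in forebrain, 48.3% in hypothalamus and 34.8% in medulla had another higher site within 50 nt. In 1000 random draws matched on the number of tested neighbours the highest shares were 22.4, 25.2 and 14.2% (permutation test, p = 0.001, the smallest the draws can give). Neighbouring sites changing together may account for it; neighbours are often read on the same fragments, so they are not independent.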
